A study of Lactiplantibacillus plantarum WCFS1 and Lactiplantibacillus plantarum with 28 samples.

How the data were processed

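RNA of L. plantarum NC8 and WCFS1 was compared on dual-channel microarrays with 10807 spots, of which 9553 carry probes of 2851 genes, with 1 to 6 spots per gene. Per the labels, cells grew in a defined medium with 12 mM glucose or ribose to an OD600 of 0.65, and RNA was labelled with Cy3 in the first channel and Cy5 in the other. The scanner values are spot intensities from ImaGene, per the file headers, with a mean signal and a local background per spot and channel, not background-subtracted. The deposited value table holds log2 ratios of Cy3 over Cy5 for each array, as tests on the values showed. The authors' normalization of that table is not given in the sources used here. Other values in the deposited scanner files are quality flags and spot coordinates. Flag 2 marks empty spots, and spots with flag 3, which marks spots the software rated poor, were left out. That reading of the flags comes from the values, and flag 3 falls mostly on bright spots.

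The groups came from the labels alone. In R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), signals were background-corrected with normexp (offset 50) and the log2 ratios were normalized by loess within arrays. A probe was used where it was well above background (mean signal over the background mean plus 2 background SD) in at least 2 channel measurements of the strain. Spots of a probe and then probes of a gene were averaged. For each gene and strain, least squares over the arrays gave 1 log2 level per RNA sample, with 1 dye term. A second limma fit with moderated variances compared group means of those levels, with 4 residual degrees of freedom in NC8 and 4 in WCFS1, and p-values were adjusted by Benjamini-Hochberg within each comparison. Errors given as SE are the moderated standard errors of this fit. The comparisons were 7 in NC8, 9 in WCFS1 and 2 between the strains, with a threshold of 0.05 on the adjusted p. cggR probes were also followed one by one, with flagged spots kept, since flag 3 covers all cggR spots of 1 NC8 and 3 WCFS1 arrays with overexpression RNA.

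Comparisons, lists, the rule for named genes and the first set of other settings were chosen before the data were examined. The rule names the cggR-gap operon genes (locus tags lp_0788 to lp_0792) in every comparison. It also names the genes with the largest rise and fall among those past the threshold whose RNA samples do not overlap between the groups. The gene average of lp_0788 is not printed in every comparison, and in the mutants it mixes opposite changes. Since 0 tags matched the reference and the files do not pair them with names, at most 2 genes per direction are printed. Of 19 lists, 1 could be tested, the operon, because the other lists were written as gene symbols and a list needs 4 measured genes. The list was tested with camera (preset correlation 0.01, and an estimated correlation beside it), with cggR and, chosen after the data were seen, without it. In NC8 the tested list holds 4 genes, since camera takes genes with a level in every RNA sample and all cggR spots of the overexpression array carry flag 3.

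The fit was tested on simulated data made from the spread in these arrays, with 100 genes changed by each size. In the NC8 mutant on glucose, over 2786 genes, it recovered 78% of changes of 0.5 and 98% of changes of 1 on the log2 scale, with 11 false calls among 187. For the WCFS1 mutant on glucose, over 2832 genes, it recovered 22% and 78%, with 7 false calls among 107. False calls were more frequent elsewhere, with 31 among 193 for NC8 overexpression, 27 among 204 for ribose against glucose in NC8 wild type and 14 among 115 in WCFS1 wild type. For WCFS1 overexpression on glucose it recovered 3% of changes of 0.5 and 64% of changes of 1. With no changed genes, the share of genes at an unadjusted p under 0.05 was 5.96% for the NC8 mutant on glucose and 10.4% for NC8 overexpression, and 11.7% for ribose against glucose in WCFS1 wild type, with 0 adjusted calls in each. With spread between arrays alone it was 17.9% for NC8 overexpression. For ribose against glucose in wild type it was then 15.9% in NC8, with 2 adjusted calls, and 14.3% in WCFS1. The simulated noise was independent between genes, so shifts shared by many transcripts were not simulated.

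The first set of other settings changed 1 choice at a time. It held no background subtraction, median centring in place of loess, scale normalization between arrays, the authors' value table, no or a stricter filter on dim probes, the median over probes, no dye term, a mixed model with RNA sample as a random effect, all arrays as independent, the duplicate letter as a block, eBayes with an intensity trend, and leaving out each RNA sample and each array. After the data were seen, settings were added with flagged spots kept, with a dye term per scan batch, within scan batches, with doubted WCFS1 arrays left out, and with a term for single channels. Scan batches were read from spot coordinates, which lie on different pixel grids. Probes that are not of genes were left out of the comparisons. The array labelled mutant glucose A against mutant ribose A in WCFS1 was kept, since labels were not changed by values.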

Results

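Transcript levels were compared on 28 dual-channel DNA microarrays of Lactiplantibacillus plantarum, a lactic acid bacterium, in the strains NC8 (12 arrays) and WCFS1 (16 arrays). Per the labels, cultures grew on glucose or ribose as the carbon source and were wild type, a cggR mutant (cggRKO in the labels), or a strain that overexpresses cggR (cggR+). CggR is known as the repressor of the operon it starts, which in this species goes on with gapB, pgk, tpiA and enoA1, the genes of the lower part of glycolysis. NC8 gave 9 RNA samples, with 2 in each of the wild-type and mutant groups on each sugar and 1 overexpression sample on glucose. WCFS1 gave 10 RNA samples, with 2 in each wild-type and mutant group and 1 overexpression sample on each sugar. Each array set 1 RNA sample in Cy3 against another in Cy5, and the arrays of a strain form linked loops. The labels do not say whether duplicates A and B are separate cultures, so the p-values measure the spread between the fitted levels of these RNA samples, which may be technical. That spread includes array error, and the fit treats levels from shared arrays as independent. In the mixed model the ratio of RNA sample variance to array variance was 0.213 in NC8 and 0.000335 in WCFS1. The WCFS1 spread was thus nearly all array error in that model. The WCFS1 ratio was estimated with all 16 arrays, whose log ratios do not add up around the loop (residual 31.0% of the squared log ratios). Such misfit counts as array error in that model. The number of arrays limits the precision. The median spot signal was 1.88 to 2.19 times its background in Cy3 and 1.67 to 2.03 times in Cy5 over the NC8 arrays. On the WCFS1 arrays it was 1.74 to 2.44 times in Cy3 and 1.52 to 2.18 times in Cy5. The 2 scan batches that spot coordinates show held 6 and 6 arrays in NC8 and 6 and 10 in WCFS1. The files give locus tags and do not pair them with gene names, so genes outside the operon fixed by tag are given as tags, and at most 2 that rose and 2 that fell are printed per comparison.

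cggR itself (lp_0788) was measured by 3 probes, and these went opposite ways in the mutants. At probe 1 the spot signal was 555 to 659 in the 12 NC8 channels labelled mutant, against 2119 to 4619 in the 11 labelled wild type, and 33340 in the overexpression channel. At probe 2 the NC8 mutant channels gave 21330 to 41648 against 2799 to 7043 in wild type, and at probe 3 they gave 5657 to 10143 against 1674 to 2622. The probe 1 signals of the NC8 mutant lie close to their background of 475 to 489, with 8 of 12 spots well above it, so the size of that fall was not measured. The probe 2 signals of the mutant reach those of the overexpression channel, where the 3 probes gave 33340 to 36973, and 13 of 24 spots carry flag 3, so they may be saturated and the size of that rise is not given. On the log2 scale, probe 3 was higher in the NC8 mutant by 2.32 on glucose and 2.65 on ribose, n = 2 RNA samples per group. In WCFS1, probe 1 gave 524 to 1018 in 12 mutant channels, 1551 to 8478 in 12 wild-type channels and 29942 to 36149 in 6 overexpression channels, while probes 2 and 3 were again higher in the mutant. The gene average of lp_0788 therefore mixes opposite changes in the mutants, and probes 2 and 3 do not check the mutant labels if they lie outside the altered part, which the files do not state. The WCFS1 array labelled mutant glucose A against mutant ribose A stood apart, with a probe 1 signal of 31892 in Cy3 and 5634 in Cy5. These lie in the ranges of the channels labelled overexpression and wild type, so directions that rest on this array are given as those of the array labelled mutant.

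**Figure D1:**
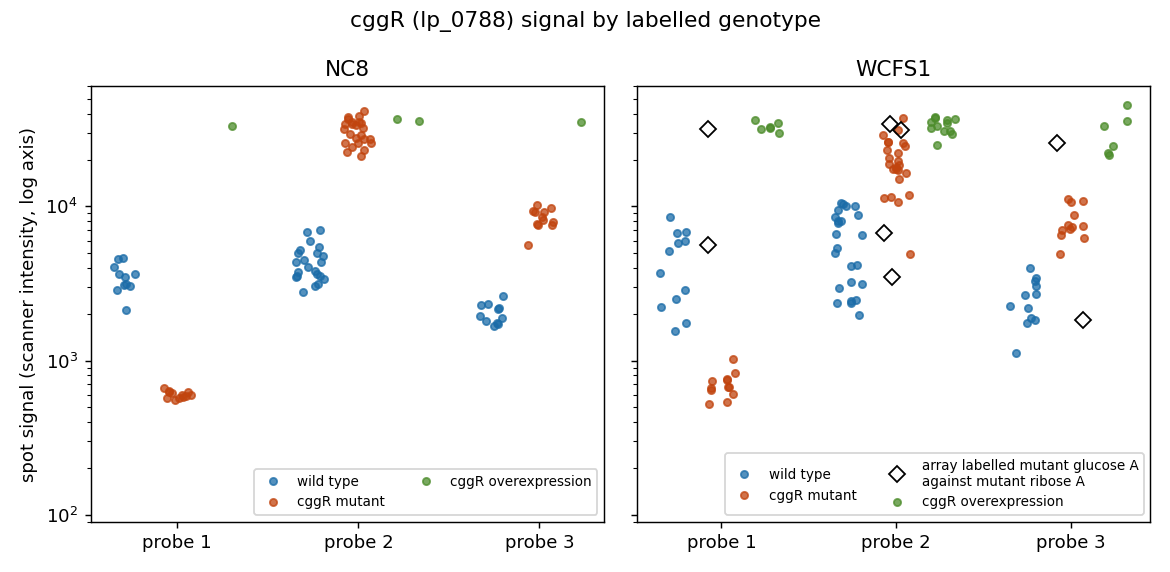
Spot signal of the 3 cggR probes on a log axis, 1 point per spot and channel, by strain and labelled genotype; black diamonds mark the WCFS1 array labelled mutant glucose A against mutant ribose A. Mutant channels of NC8 sit at 555 to 659 at probe 1 and above the wild-type channels at probes 2 and 3.

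Overexpression of cggR in NC8 on glucose lowered the gap operon, which asks what more of the regulator does to the genes it is known to control. All 4 measured genes downstream of cggR fell, with log2 changes of -0.71 for gapB (SE 0.11), -0.83 for pgk (SE 0.09), -0.88 for tpiA (SE 0.08) and -0.58 for enoA1 (SE 0.12), 1 overexpression sample against 2 wild type. These genes encode glyceraldehyde-3-phosphate dehydrogenase, phosphoglycerate kinase, triosephosphate isomerase and enolase, and their mean change was -0.75 (SD 0.13 over the 4 genes). Outside the operon, lp_0655 rose by 2.53 (SE 0.21) and lp_3023 rose by 2.02 (SE 0.12), while lp_0404 fell by 3.65 (SE 0.36) and lp_0406 fell by 2.70 (SE 0.33). By limma, 245 genes were higher and 233 lower of 2789 tested (adjusted p under 0.05). The adjusted p of the 4 operon genes ran from 2.2e-05 to 0.00637, and 4 were past the threshold when adjusted over the list alone. As a set (camera) the operon was lower with p = 3.63e-06 at the preset correlation, and p = 0.0469 with an estimated correlation. The lone overexpression sample was measured on 1 array, in 1 dye, and is assumed to vary like the other groups. Array error of that hybridisation therefore cannot be told from the effect of overexpression. Fewer genes were called in the mixed model and with all arrays as independent. The count was 513 with a dye term per scan batch, 506 within the first scan batch, and 176 without the array labelled mutant ribose B against mutant ribose A, the lowest of the single omissions.

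Loss of cggR in NC8 went with higher gap operon transcripts on ribose. On ribose all 4 genes rose in the mutant, by 0.32 for gapB (SE 0.09), 0.47 for pgk (SE 0.08), 0.41 for tpiA (SE 0.06) and 0.30 for enoA1 (SE 0.10), 2 RNA samples per group. On glucose their changes were 0.22, 0.11, 0.11 and 0.28, and 0 of the 4 passed the limma threshold over all genes or when adjusted over the list alone. Averaged over both sugars the 4 genes rose by 0.26 to 0.29, with adjusted p from 0.00295 to 0.0158. When adjusted over the list alone, 4 passed on ribose and 4 in the average. As a set the operon was higher on glucose (camera p = 0.00287, and p = 0.142 with an estimated correlation), on ribose (p = 0.00225, and p = 0.135 with an estimated correlation) and in the average (p = 9.27e-05, and p = 0.0747 with an estimated correlation). The rise of gapB on ribose missed the threshold in 5 of 36 alternatives and omissions, and that of enoA1 in 13.

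**Figure D2:**
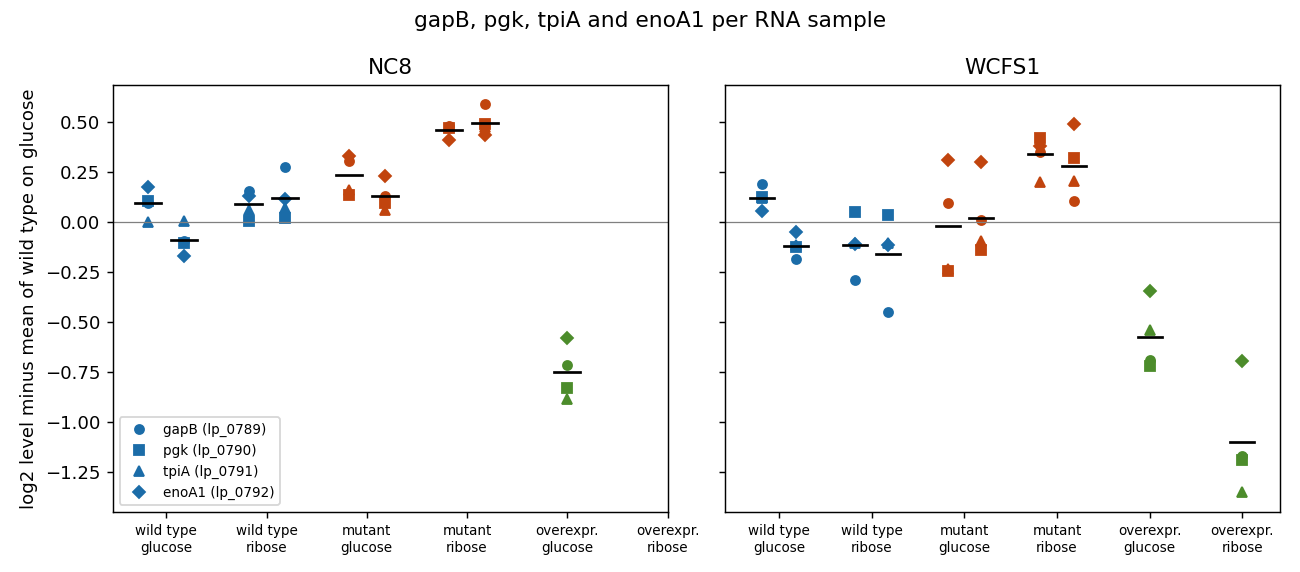
Log2 level of gapB, pgk, tpiA and enoA1 in each RNA sample, relative to the mean of wild type on glucose in the same strain; symbols are genes and black bars are means over the 4 genes. The overexpression samples have the lowest means, -0.75 in NC8 and -0.57 and -1.10 in WCFS1.

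The NC8 mutant differed from wild type at few genes on glucose and at many on ribose. On glucose lp_0371 fell by 2.45 (SE 0.11) and lp_2154 fell by 1.77 (SE 0.08), and lp_0166 rose by 0.48 (SE 0.07) and lp_1805 by 0.39 (SE 0.08), 2 RNA samples per group, with these rises past the threshold no more in 3 and 14 of 36 alternatives and omissions. On ribose lp_0372 rose by 2.29 (SE 0.10) and lp_0371 rose by 2.12 (SE 0.11), while lp_3023 fell by 2.71 (SE 0.10) and lp_3022 fell by 2.19 (SE 0.08). Averaged over the sugars, lp_0575 rose by 0.60 (SE 0.05) and lp_0889 by 0.56 (SE 0.05), and lp_3023 fell by 1.38 (SE 0.07) and lp_0960 fell by 1.12 (SE 0.06), 4 RNA samples per genotype. The average of lp_3023 comes nearly all from ribose, where its change was -2.71 and its genotype by sugar interaction -2.66. By limma, 2 genes were higher and 39 lower on glucose of 2794 tested, 386 higher and 419 lower on ribose of 2793, and 153 higher and 256 lower in the average. With scale normalization between arrays the average gave 58 higher and 158 lower. With a dye term per scan batch the counts were 39, 799 and 414, and with the duplicate letter as a replicate block 46, 874 and 468. All arrays of the glucose loop lie in the first scan batch, which alone gave 52 genes, and the ribose loop lies in the second, which alone gave 357. The lowest counts came without the array labelled mutant ribose B against mutant ribose A, at 21, 448 and 148. The highest were 143 and 572, without wild type glucose A against mutant glucose A, and 915 on ribose without mutant ribose A against wild type ribose A.

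The mutant effect in NC8 differed between the glucose and the ribose samples, which the interaction of genotype and sugar tests. Arrays that set mutant against wild type lie in the first scan batch for glucose and in the second for ribose. Scan batch therefore cannot be fully separated from sugar here, and a dye term per batch does not separate them. The largest interactions were in lp_0371, whose mutant effect was 4.57 higher on ribose than on glucose (SE 0.16), and lp_0372, with 3.50 (SE 0.15). In the other direction stood lp_3023, with -2.66 (SE 0.14), and lp_3022, with -2.34 (SE 0.11), 2 RNA samples per group. Among the operon genes, pgk had an interaction of 0.35 (SE 0.11, adjusted p = 0.0366) and tpiA of 0.30 (SE 0.09, adjusted p = 0.0384), while gapB had 0.10 and enoA1 0.02. Both were also past the threshold when adjusted over the list alone, but their calls were lost in 18 and 16 of 35 alternatives and omissions. As a set the operon had camera p = 0.109, and p = 0.382 with an estimated correlation. By limma, 265 genes had a positive and 307 a negative interaction of 2793 tested. The count was 599 with a dye term per scan batch, and neither scan batch holds all 4 groups. It ranged from 247, without the array labelled mutant ribose B against mutant ribose A, to 616, without wild type ribose A against wild type glucose A.

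**Figure D3:**
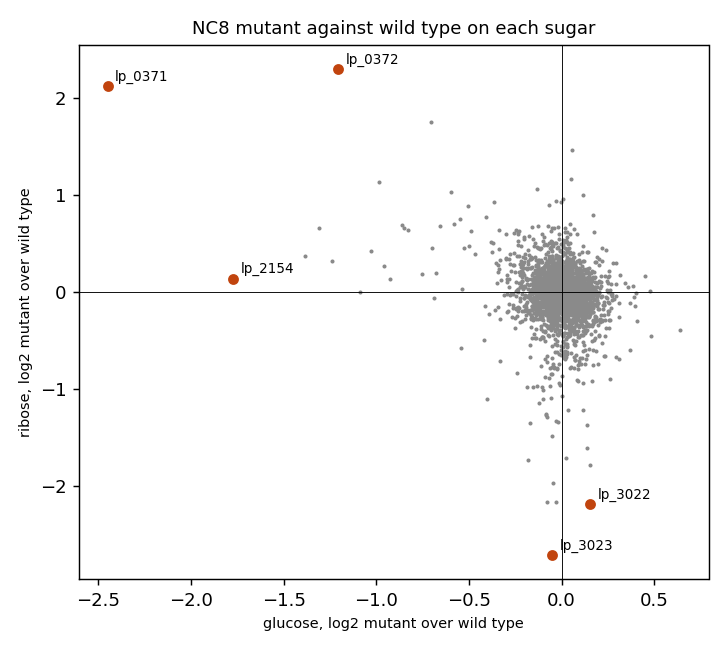
Log2 change of the NC8 mutant against wild type on glucose (horizontal) and on ribose (vertical), 1 point per gene, with 5 genes marked. lp_0371 lies at -2.45 on glucose and 2.12 on ribose, and lp_3023 fell by 2.71 on ribose.

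Growth on ribose in place of glucose changed about as many genes in the NC8 mutant as in the wild type. In wild type lp_3659 rose by 6.69 (SE 0.08) and lp_3658 by 6.26 (SE 0.09), while lp_0575 fell by 2.86 (SE 0.07) and lp_0576 fell by 2.64 (SE 0.08), 2 RNA samples per group. In the mutant lp_3540 rose by 7.10 (SE 0.10) and lp_3541 by 7.0 (SE 0.07), while lp_0349 fell by 2.33 (SE 0.10) and lp_3134 fell by 1.93 (SE 0.14). The gap operon genes had a mean change of 0.10 in wild type (SD 0.09 over the 4 genes), where 0 of 4 passed the limma threshold and 0 passed when adjusted over the list alone. This mean was -0.26 with median centring in place of loess. In the mutant, gapB rose by 0.32 (SE 0.09), pgk by 0.36 (SE 0.08) and tpiA by 0.36 (SE 0.06), and 3 were past the threshold when adjusted over the list alone. Their mean with enoA1 went from 0.30 to 0.10 with median centring, where 0 of the 4 were past the threshold over all genes. The set test gave camera p = 0.610 in wild type, and p = 0.771 with an estimated correlation, and in the mutant p = 0.0687, and p = 0.328 with an estimated correlation. By limma, 794 genes were higher and 631 lower in wild type of 2793 tested, and 697 higher and 696 lower in the mutant of 2794. With a dye term per scan batch the counts were 1411 and 1387, and with scale normalization between arrays 915 and 751. Within the first scan batch the wild type gave 1162, and within the second the mutant gave 930.

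**Figure D4:**
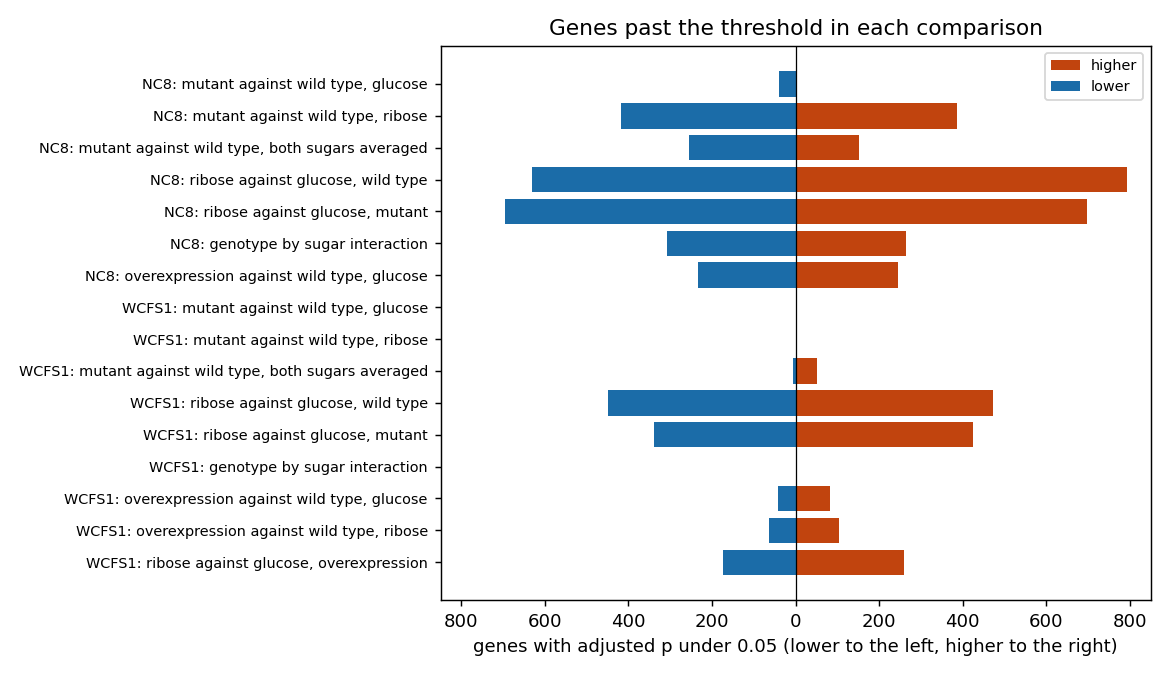
Number of genes with adjusted p under 0.05 (limma) in each comparison within a strain, lower to the left and higher to the right of 0. The NC8 sugar comparisons have the longest bars, with 794 genes higher and 631 lower in wild type.

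In WCFS1, overexpression of cggR lowered pgk and tpiA on glucose and all 4 downstream operon genes on ribose. On glucose the changes were -0.69 for gapB (SE 0.17, adjusted p = 0.0617), -0.72 for pgk (SE 0.12, adjusted p = 0.0136), -0.54 for tpiA (SE 0.11, adjusted p = 0.0374) and -0.34 for enoA1 (SE 0.09, adjusted p = 0.0821), 1 overexpression sample against 2 wild type. On ribose they were -0.80 for gapB (SE 0.17), -1.23 for pgk (SE 0.12), -1.24 for tpiA (SE 0.11) and -0.58 for enoA1 (SE 0.09), with adjusted p from 0.00271 to 0.0344. When adjusted over the list alone, 4 of these genes passed on glucose and 4 on ribose. Outside the operon on glucose, lp_3387 rose by 2.67 (SE 0.27) and lp_3379 by 2.38 (SE 0.23), and lp_1084 fell by 1.04 (SE 0.10) and lp_3271 fell by 1.01 (SE 0.08). On ribose lp_1577 rose by 1.47 (SE 0.34) and lp_3379 by 1.46 (SE 0.23), and lp_1169 fell by 1.73 (SE 0.19) and lp_3547 fell by 1.35 (SE 0.31). The set test of the 4 genes without cggR gave camera p = 1.89e-05 on glucose, and p = 0.0562 with an estimated correlation, and on ribose p = 2.02e-07, and p = 0.0318 with an estimated correlation. With cggR, which rose itself, the list gave p = 0.0228 on glucose, and p = 0.235 with an estimated correlation, and on ribose p = 0.00153, and p = 0.124 with an estimated correlation.

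By limma, the WCFS1 overexpression samples had 83 genes higher and 42 lower on glucose and 104 higher and 64 lower on ribose, of 2841 tested. The authors' value table gave 108 higher and 89 lower on glucose. With a dye term per scan batch the counts were 52 and 12, and the second scan batch alone gave 21 on ribose. In the first scan batch 1 wild-type sample per sugar links to an overexpression sample, so no test was run there. Both limma counts fell to 0 without the array labelled mutant ribose B against mutant ribose A, where 203 and 206 genes had an unadjusted p under 0.05, and the ribose count also without mutant glucose A against mutant glucose B, where 209 did. Each lone overexpression sample is assumed to vary like the other groups and has no spread of its own, and the left-out arrays just named hold neither an overexpression nor a wild-type sample. The ribose calls were also all lost without wild type ribose A against wild type ribose B, which holds both wild-type samples of that comparison. The call of tpiA on glucose was lost in 21 of 42 alternatives and omissions, that of gapB on ribose in 20 of 41, and that of lp_1577 in 22 of 43, with 2 more in which it turned to a fall. The highest counts were 194, without wild type glucose A against overexpression glucose A, and 422, without wild type ribose A against overexpression ribose A. Without the array labelled mutant glucose A against mutant ribose A they were 157 and 287.

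Fitted without pairing, the WCFS1 mutant differed from wild type at few genes. On ribose enoA1 rose by 0.55 (SE 0.07, adjusted p = 0.0496), lp_3170 by 1.26 (SE 0.11, adjusted p = 0.00978) and lp_0616 by 0.69 (SE 0.09, adjusted p = 0.0496), 2 RNA samples per group. The other operon genes had changes on ribose of 0.60 for gapB (SE 0.14), 0.33 for pgk (SE 0.10) and 0.31 for tpiA (SE 0.09), and 4 passed when adjusted over the list alone. On glucose gapB, pgk, tpiA and enoA1 had 0.05, -0.19, -0.17 and 0.30, with 1 past the threshold when adjusted over the list alone. Averaged over the sugars, enoA1 rose by 0.42 (SE 0.05, adjusted p = 0.0150), with 2 of the 4 past the threshold when adjusted over the list alone. In that average lp_2126 rose by 1.35 (SE 0.26) and lp_2125 by 1.34 (SE 0.25), and lp_1045 fell by 0.40 (SE 0.06) and lp_1197 fell by 0.35 (SE 0.06), 4 RNA samples per genotype. The 4 genes without cggR gave camera p = 0.997 on glucose, and p = 0.998 with an estimated correlation, on ribose p = 2.16e-05, and p = 0.0573 with an estimated correlation, and in the average p = 0.00597, and p = 0.163 with an estimated correlation. This shorter list was chosen after the data were seen. The list as fixed, with cggR, gave camera p = 0.456 on glucose, and p = 0.671 with an estimated correlation. On ribose it gave p = 0.00350, and p = 0.148 with an estimated correlation. In the average it gave p = 0.113, and p = 0.386 with an estimated correlation. Thus only the shorter list had p under 0.05 in the average, and only at the preset correlation.

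By limma, the WCFS1 mutant had 0 genes past the threshold on glucose, where 325 had an unadjusted p under 0.05, 4 higher and 0 lower on ribose, where 460 did, and 52 higher and 7 lower in the average, of 2841 tested. These counts rested on single arrays and on how the duplicates are treated. With the duplicate letter as a replicate block they were 17, 126 and 218. Across genes the difference between A and B had r of 0.34 on glucose and 0.61 on ribose between mutant and wild type. These levels come from linked arrays, so array error alone can correlate such differences, and r does not show that the letters pair. The labels do not say whether the letters pair the cultures. With a dye term per scan batch the limma counts were 0, 0 and 0, and 118, 267 and 302 genes had an unadjusted p under 0.05. Within the second scan batch they were 0, 0 and 0, with 413, 149 and 94 at an unadjusted p under 0.05. The glucose count was 159 without the array labelled mutant glucose A against wild type glucose A, and the average was then 451. The ribose count was 350 without mutant ribose A against wild type ribose A, and 0 (407 unadjusted) without wild type ribose B against mutant ribose B, which also took the average to 0 (243 unadjusted), with lp_2126 at -0.29. The ribose and averaged counts were also 0 without mutant glucose B against wild type glucose B (197 and 257 unadjusted). They were 0 too without mutant glucose A against mutant glucose B (62 and 126 unadjusted). The same held without mutant ribose B against mutant ribose A (100 and 150 unadjusted). It held as well without wild type ribose A against wild type ribose B (136 and 122 unadjusted). The calls of enoA1 and lp_0616 on ribose were each lost in 27 of 44 alternatives and omissions.

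The interaction of genotype and sugar in WCFS1 had 0 genes past the threshold by limma, and 125 had an unadjusted p under 0.05. The operon genes had interactions of 0.55 for gapB (SE 0.19), 0.52 for pgk (SE 0.14), 0.48 for tpiA (SE 0.13) and 0.24 for enoA1 (SE 0.10), 2 RNA samples per group. When adjusted over the list alone, 3 passed. The 4 genes without cggR gave camera p = 1.34e-06, and p = 0.0396 with an estimated correlation, and with cggR p = 6.70e-05, and p = 0.0706 with an estimated correlation. The count was also 0 with a dye term per scan batch, where 69 genes had an unadjusted p under 0.05 by limma, and within the second scan batch, where 521 did. The mean interaction of the 4 operon genes, 0.45 with all arrays, was 0.09 within the second scan batch, and over all settings pgk ran down to -0.03 and tpiA to -0.20. The count stayed at 0 in each of the 26 omissions of 1 RNA sample or array.

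Ribose in place of glucose raised and lowered many WCFS1 genes in wild type and in the mutant. In wild type lp_3658 rose by 6.02 (SE 0.41) and lp_3539 by 5.72 (SE 0.39), while lp_0349 fell by 1.99 (SE 0.23) and lp_0329 fell by 1.71 (SE 0.17), 2 RNA samples per group. In the mutant lp_3659 rose by 4.66 (SE 0.42) and lp_3658 by 4.60 (SE 0.41), while lp_0349 fell by 1.43 (SE 0.23) and lp_0214 fell by 1.25 (SE 0.14). That mutant fit includes the array labelled mutant glucose A against mutant ribose A. Over the alternatives and omissions lp_3659 ran from 2.76 to 6.60 and lp_3658 from 2.59 to 6.51 in the mutant. In wild type lp_3658 ran from 2.08 to 6.92 and lp_3539 from 0.45 to 6.79. In the overexpression samples lp_3659 rose by 4.97 (SE 0.60) and lp_3658 by 4.92 (SE 0.59), while lp_0576 fell by 2.09 (SE 0.15) and lp_0577 fell by 2.00 (SE 0.19). That last comparison sets 1 RNA sample against 1, so neither group has a spread of its own, and its SE and calls assume that both samples vary like the other groups. Among the operon genes, pgk rose by 0.56 (SE 0.10) and tpiA by 0.37 (SE 0.09) in the mutant, and tpiA was lower by 0.81 in the lone overexpression sample on ribose than in that on glucose. Without the array labelled mutant glucose A against mutant ribose A, the mutant mean over the 4 genes went from 0.31 to 0.13. Over the alternatives and omissions pgk ran down to 0.28, and the call of tpiA was lost in 19 of 45. In wild type cggR (lp_0788) itself had a change of -0.86 (SE 0.21, adjusted p = 0.0152 by limma). That call was lost in 12 of 41 alternatives and omissions. Of the 4 genes downstream of cggR, 0 passed the limma threshold in wild type, with a mean of -0.14 (SD 0.17 over the 4 genes). This mean was -0.46 with median centring and -0.23 without the array labelled mutant glucose A against mutant ribose A. It was 0.53 within the second scan batch, but only that array links the sugars there, so 0.53 may not measure the sugars. Up to 2 of the 4 genes passed the threshold over the settings. With 0 of 4 past it in the main fit, the direction of the mean is not settled. Of the 4 genes downstream of cggR, when adjusted over the list alone, 0 passed in wild type, 2 in the mutant and 4 in the overexpression samples. The 4 genes without cggR gave camera p = 0.353 in wild type, and p = 0.595 with an estimated correlation, in the mutant p = 0.0407, and p = 0.272 with an estimated correlation, and in the overexpression samples p = 0.00183, and p = 0.125 with an estimated correlation. The list as fixed, with cggR, gave p = 0.164 in wild type, and p = 0.441 with an estimated correlation, in the mutant p = 0.269, and p = 0.535 with an estimated correlation, and in the overexpression samples p = 0.00669, and p = 0.171 with an estimated correlation.

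By limma, ribose against glucose in WCFS1 gave 472 genes higher and 448 lower in wild type, 425 higher and 338 lower in the mutant, and 259 higher and 174 lower between the lone overexpression samples, where the spread comes wholly from the other groups. With a dye term per scan batch the counts were 669, 433 and 156. Within the second scan batch they were 1264 in wild type and 441 in the mutant, but there the sugars are linked only by the array labelled mutant glucose A against mutant ribose A, and lp_0349 turned to a rise of 1.31 in wild type and 1.29 in the mutant. Without that array the counts were 1210, 1253 and 752. Without the array labelled mutant ribose B against mutant ribose A they were 253, 33 and 0, the last with 341 genes at an unadjusted p under 0.05 by limma.

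The strains answered the sugars alike at many genes. Across 2787 genes measured in both, the wild-type ribose against glucose changes had r = 0.69, and genes are not independent replicates. Of the genes called in both strains, 276 were higher in both and 243 lower in both, against 129.7 and 100.1 for independent lists, and 53 went opposite ways. In the mutants, 274 were higher in both and 232 lower in both, against 103.1 and 84.3 for independent lists, and 22 went opposite ways. Overexpression on glucose gave 19 genes higher in both and 18 lower in both, against 6.78 and 3.52 for independent lists, and 0 went opposite ways. For the mutation, the WCFS1 calls are too few to share many genes. On glucose the mutant effects had r = 0.10 across genes, and 12.2% of the 41 NC8 calls had the same sign in WCFS1. The mutant effects on ribose had r = -0.15 across genes, with 1 gene higher in both against 0.553 for independent lists, 0 lower in both and 2 that went opposite ways, and 35.5% of the NC8 calls had the same sign in WCFS1. In the sugar average r was -0.04, with 3 genes higher in both and 2 lower in both, against 2.85 and 0.643 for independent lists, and 6 opposite. Averaged over the sugars, the change of lp_3023 in the mutant differed by -1.41 (NC8 minus WCFS1, SE 0.09) and that of lp_0865 by -1.36 (SE 0.34), while lp_3060 had a difference of 0.60 (SE 0.11) and lp_2542 of 0.55 (SE 0.09). For ribose against glucose in wild type, 2 RNA samples per group, lp_3023 had a difference of 2.43 (SE 0.13) and lp_0960 of 2.00 (SE 0.12). There lp_3569 had -4.85 (SE 0.46) and lp_3570 -3.94 (SE 0.42). Over the alternatives and omissions lp_3569 ran from -5.85 to -0.42, with its call lost in 0 of 62. For the mutation lp_0865 ran from -1.72 to -0.04, with its call lost in 12 of 62. The operon's gapB differed by 0.58 (SE 0.17, adjusted p = 0.0265) for the sugars in wild type, and 1 of the 4 passed when adjusted over the list alone. That call was lost in 15 of 60 alternatives and omissions and turned direction in 1. For the mutation 0 of 4 passed the limma threshold over all genes or over the list. For the sugars in wild type, cggR (lp_0788) differed by 0.745 (SE 0.25, adjusted p = 0.0459 by limma). The cggR call was lost in 32 of 59 alternatives and omissions and turned direction in 1.

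Tested directly by limma, the mutant effect averaged over the sugars was higher in NC8 than in WCFS1 at 140 genes and lower at 254 of 2787, and the wild-type sugar effect was higher at 374 and lower at 332. With a dye term per scan batch these counts were 134 and 640, and with the second WCFS1 scan batch alone 63 and 1564. In that batch the sugars are linked only by the array labelled mutant glucose A against mutant ribose A, so 1564 may not measure the sugars. Both counts of the main fit fell, to 30 and 255, without the WCFS1 array labelled mutant ribose B against mutant ribose A. The first was 668 without mutant glucose A against wild type glucose A, and the other was 1048 without wild type ribose A against wild type glucose A.

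**Figure D5:**
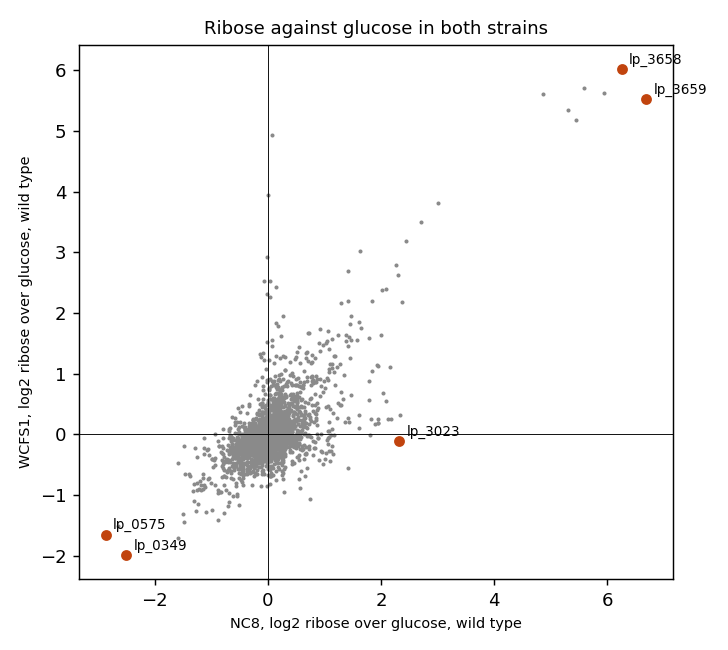
Log2 change of ribose against glucose in wild type in NC8 (horizontal) and WCFS1 (vertical), 1 point per gene, with 5 genes marked. lp_3658 rose by 6.26 in NC8 and by 6.02 in WCFS1, and r across genes was 0.69.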

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

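All tests of explanations in this part were chosen after the result was seen, and the regroupings of the samples were planned, with the limit to splits that keep the sugars even added after they were seen. In NC8, 572 genes had a genotype by sugar interaction past the threshold, which marks a mutant effect that differs between the sugars or between the scan batches that hold them. Among the operon genes this held for pgk (lp_0790, 0.35) and tpiA (lp_0791, 0.30). The mutant effect averaged over the sugars differed between the strains at 394 genes and the wild-type sugar effect at 706, with gapB (lp_0789) differing by 0.58 for the sugars. Probes outside the gene comparisons had signal well above background more often than the 656 blank spots, where 0.0327% of measurements passed. The share was 100% for RFN_2, 98.2% for SRP, 85.7% for THI_1, 99.1% for THI_2, 10.7% for antilp_1220, 14.3% for antilp_3468 and 32.1% for antilp_3469.

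Regrouping the same RNA samples tested the counts of the mutant averaged over the sugars, first over the 34 splits per strain that could be fitted. Of these, 2 in NC8 gave as many genes as the real one (highest other 572) and 1, the real one, in WCFS1 (highest other 17), and for the difference between the strains 1 of 100 drawn, the real one, did (highest other 236). As 16 of the 34 are uneven in sugar, which the real split is not, the test was repeated without them. That leaves 18 splits per strain, too few for a share under 0.05. In NC8, 2 of 18 gave as many genes as the real split (409), and the other, with 572 genes, crosses genotype with sugar and so measures the interaction, which points to a structure of the samples. Splits that kept the genotypes apart on ribose and mixed them on glucose gave 196 to 336 genes. Those that did the reverse gave 1 or 2, so the NC8 average rests mostly on ribose. In WCFS1, 1 of 18, the real one, gave as many as 59 genes and the highest other gave 0, while the count was 0 with a dye term per scan batch (302 unadjusted, limma) and without wild type glucose A (362 unadjusted, limma). For the difference between the strains (394 genes), 3 of 100 drawn regroupings, the real one included, gave as many, and the highest other gave 670. In each draw the share with as many genes was under 0.05. That share cannot exclude chance, because other splits put the genotype difference into their spread, which lowers their counts. In the second draw both higher counts cross genotype with sugar in NC8. Leaving out single RNA samples or arrays moved the count from 30 to 668. It was 26 in the mixed model and 35 with all arrays as independent.

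The log ratios of the WCFS1 arrays did not add up around the loop, with a residual of 31.0% of the squared log ratios against 2.73% in NC8, and 20.9% without the array labelled mutant glucose A against mutant ribose A. A set of 100 transcripts, picked on other arrays as lower in the second scan batch, differed by 1.27 (log2) between the 2 channels that hold wild type ribose B, against at most 0.23 within any NC8 RNA sample, which argues against differences between RNA samples as the whole cause. On 3 arrays of the second scan batch, with wild type ribose in Cy3, it was at least 1.04 higher in Cy5 than in Cy3. On the other WCFS1 arrays this was at most 0.33, which argues against a change covering whole arrays. Wild type ribose A against wild type glucose A, in the first batch, also has wild type ribose in Cy3, with 1.29 in Cy3 and 1.24 in Cy5. The 3 arrays were chosen after the data were seen. A labelling difference in single channels may remain, since 1 term for these 3 Cy3 channels lowered the residual outside the set from 17.9% to 9.16%, but 11 of 455 sets of 3 arrays, these included, did as well and the lowest reached 7.19%. It stays open, because the labels give no labelling batch, and strain or growth differences were tested only through the RNA samples.

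The WCFS1 array labelled mutant glucose A against mutant ribose A had cggR probe 1 signals 5.53 times or more above the highest of the other 12 mutant channels. Mutant cultures that carry cggR are argued against by the same RNA samples on other arrays, where their highest signal was 1018, below the lowest wild-type signal of 1551. A swap with another array of the series is argued against by the other 15 arrays, on which the lowest wild-type signal was 1.52 times the highest mutant signal. Its log ratios had an absolute r of at most 0.11 across genes with the other 3 ribose against glucose arrays, which had 0.77 to 0.87 among themselves. Another hybridisation under this label may account for both values, as a hypothesis.

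In both mutants cggR probe 1 was lower and probes 2 and 3 were higher than in wild type. Spots rated poor by the software are argued against, since in the spots without that mark, and without the array in doubt, probes 2 and 3 were still higher by at least 1.37 (log2 of signal minus background) in both strains and sugars. Transcription of the part of the gene that remains in the mutants may account for it, as a hypothesis. With flagged spots kept, the rise of the group means was at least 1.87 over both probes, strains and sugars, with or without the array in doubt. What drives such transcription, and cross-hybridisation of the probes, were not tested, since the files hold no sequences.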

How the results depend on the processing

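The alternatives with flagged spots kept, a dye term per scan batch, within scan batches, with doubted WCFS1 arrays left out, with a term for single channels and with a crossed block were chosen after seeing the data, and the others were fixed first. The scanner's own log ratio was not run because the files hold no such column, and a dye term per slide was not run because they name no slide. Signal over background near 2 limits what dim probes can show. Leaving out single RNA samples or arrays, the counts of genes past the threshold ranged as follows in NC8: mutant on glucose 21 to 143, on ribose 448 to 915, averaged 148 to 572, ribose against glucose in wild type 1039 to 1482 and in the mutant 1018 to 1432, interaction 247 to 616, overexpression 176 to 480. In WCFS1 they ranged from 0 to 159 for the mutant on glucose, 0 to 350 on ribose, 0 to 451 averaged, 253 to 1210 for ribose against glucose in wild type, 33 to 1253 in the mutant, 0 to 752 in the overexpression samples, 0 to 0 for the interaction, and for overexpression 0 to 194 on glucose and 0 to 422 on ribose. Between the strains the range was 30 to 668 for the mutation and 252 to 1048 for the sugars. A count moved by more than 1.5 times in 130 of these fits, 25 of them in NC8, and stayed within that in 333. For the other settings fixed first, 168 counts stayed within 1.5 times of the reported one and 48 did not, and for the added settings 54 stayed and 30 did not. For all results that changed, the cause was not tested.

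Without background subtraction, the NC8 mutant on glucose gave 21, and in WCFS1 the mutant gave 1 on ribose and 37 averaged, overexpression 74 on glucose and 83 on ribose, and ribose against glucose in overexpression 241. With scale normalization between arrays, the NC8 mutant gave 448 on ribose and 216 averaged, ribose against glucose 915 in wild type and 751 in the mutant, the interaction 287, WCFS1 overexpression on ribose 312, its ribose against glucose 237, and the strain difference of the mutation 217. The authors' value table gave 262 for the NC8 mutant averaged, 318 for NC8 overexpression, and in WCFS1 0 for the mutant on ribose (548 unadjusted, limma), 197 and 344 for overexpression on glucose and ribose, and 737 for its ribose against glucose. In the mixed model, NC8 overexpression gave 168, and in WCFS1 the mutant gave 0 on ribose and 0 averaged (101 and 174 unadjusted, limma), ribose against glucose 313 in wild type, 330 in the mutant and 229 in overexpression, overexpression 42 and 23, and the strain differences 26 and 109. With all arrays as independent the same counts were 130, 0, 0 (101 and 174 unadjusted, limma), 314, 332, 229, 42, 23, 35 and 127. Median centring gave 1 on ribose and 31 averaged for the WCFS1 mutant, the median over probes gave 1 on ribose, and no dye term gave 32.

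The labels do not say whether the duplicate letters pair the cultures. The differences between A and B had correlations of -0.15 to 0.61 between groups in WCFS1 and -0.06 to 0.31 in NC8. Levels fitted from linked arrays share array error, so these correlations do not show whether the letters pair. As a replicate block the letters gave 17 for the WCFS1 mutant on glucose, 126 on ribose, 218 averaged and 345 for overexpression on ribose, while NC8 overexpression gave 563 and the other counts were within 1.5 times. With the letters of the mutant ribose samples crossed, ribose against glucose in the WCFS1 mutant gave 697.

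Among the added alternatives, keeping flagged spots gave 17 for the WCFS1 mutant on ribose, and the second NC8 scan batch gave 357 for the mutant on ribose. A dye term per scan batch gave in WCFS1 0 on ribose and 0 averaged for the mutant (267 and 302 unadjusted, limma), 433 for ribose against glucose in the mutant and 156 in overexpression, 52 and 12 for overexpression, and 134 for the strain difference of the mutation. Without the array labelled mutant glucose A against mutant ribose A, the WCFS1 mutant on ribose gave 20, ribose against glucose 1253 in the mutant and 752 in overexpression, and overexpression on ribose 287. With 4 doubted arrays left out these were 0 (316 unadjusted, limma), 1202, 670 and 288, the mutant averaged 0 (418 unadjusted, limma) and the strain difference 202. The term for 3 Cy3 channels gave 1, 1282, 408 for overexpression on ribose, 7 averaged and 252 for the strain difference. The second WCFS1 scan batch gave 0 on ribose and 0 averaged (149 and 94 unadjusted, limma), 441 for ribose against glucose in the mutant, 21 for overexpression on ribose, and 63 and 1564 between the strains.

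These genes turned direction. In the WCFS1 mutant, ribose against glucose, lp_0788 was 0.17 without the doubted array and 0.0378 with 12 arrays and 0.0378 with the Cy3 term, against -1.05, and over single omissions it ran from -2.09 to 0.17, while lp_0349 was 1.29 in the second scan batch, where wild type had 1.31. lp_1577 in overexpression on ribose was -0.15 with 12 arrays and -0.0469 with the Cy3 term. In the mutant average lp_2126 was -0.29 and lp_2125 -0.0048 without the array labelled wild type ribose B against mutant ribose B, and over single omissions they ran up to 1.83 and 1.72. Between the strains, for the sugars, lp_0788 was -0.0562 without mutant ribose A against wild type ribose A and lp_0789 was -0.0451 with the second scan batch. That batch links the WCFS1 sugars only through the doubted array, which also bears on its values of lp_0349. Of the named genes' other values, 5066 in the settings fixed first kept their label, 454 were weaker and 87 stronger.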

Other observations

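Genes called in the same direction often had neighbouring locus tags. In the NC8 mutant on ribose, 391 of 796 called genes had a gene with an adjacent tag called the same way, against a mean of 167.9 and a highest of 217 in 1000 permutations of the calls over the tags, and the longest run held 11 genes. In WCFS1 overexpression on glucose it was 70 of 125, against a mean of 4.66 and a highest of 17, with a longest run of 9. For ribose against glucose in wild type it was 883 of 1409 in NC8 (permuted mean 504.4) and 503 of 911 in WCFS1 (permuted mean 216.7). In the WCFS1 mutant averaged over the sugars it was 6 of 57, above the permuted mean of 1.398 but within the permutations, whose highest was 10.

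Of 38 genes with plasmid tags lp_p3, 32 passed the signal filter in NC8 and 38 in WCFS1. The filter asks for a probe well above background in at least 2 channel measurements, so passing it does not show expression. The lp_p3 genes had a median signal over background of 1.17 in NC8 and 2.04 in WCFS1, while chromosomal tags had 1.98 and 2.00. Of 2851 genes on the array, 2798 passed the signal filter in NC8 and 2849 in WCFS1.

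The deposited log2 ratios had r of 0.76 to 0.99 with those recomputed from each array's own scanner file. The lowest, 0.76, was the WCFS1 array labelled mutant glucose B against mutant ribose B.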
